A study of Mus musculus with 7 samples.

How the data were processed

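RNA sequencing of sorted lung cells was deposited as 1 table of 35641 genes, with 4 HF libraries and 3 libraries labelled LF. Per the labels' protocols, RNA was isolated with TRIzol LS and libraries were made with a SMART-Seq kit. The submitters' processing notes name STAR 2.6.1b, featureCounts 1.6.3 and DESeq2 1.20.0, with no roles or settings. The genome build and annotation are not given in the sources used here, so no coordinates are printed, and whether counting used strand is not given either.

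Per the name of the deposited table, the values of each library are normalized counts, a signal that is never negative. All values (100% in each library, within 0.01 of a whole number) were whole multiples of the value of 1 read, so whole reads were recovered. From this it was inferred that the authors divided gene counts by 1 size factor per library. Recovered reads came to 15805742, 13943173, 16599658 and 15216756 in HF replicates 1 to 4, and to 17464615, 16974428 and 18983351 in the LF columns. Per the file headers, the table also holds the authors' log2 fold changes with their errors, a test statistic (a score) and p-values with adjusted p-values. These columns were used only where the authors' deposited table is named.

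Columns HF1 to HF4 match the labels of the HF samples. The LF columns are numbered 6, 7 and 8, while the labels number the LF samples 1 to 3. They were taken as libraries of the LF group with no replicate number of their own, and are named LF6, LF7 and LF8. No column of a library was left out (0 unmapped columns). The design text counts mice per group, 4 HF and 3 LF, and the p-values measure the spread between these libraries.

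Choices of tests, gene lists and alternatives were fixed before the data were examined. Genes with a mean of at least 10 normalized counts over all libraries were tested on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3 (trend=TRUE), HF against LF, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of mean values on that log2 scale. The pseudocount understates the change of low genes, while for genes uneven between the libraries of a group the difference can exceed the log2 ratio of the means. Values are means ± SD over libraries. Of 43 gene lists of functions and cell types, the 42 with at least 4 tested members were tested with camera (correlation of 0.01 between genes), with camera at an estimated correlation and with fry beside it. Bounds against a group with 0 reads use a floor of 3 reads over the group, and cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

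The genes named are of 3 kinds. First come the 12 with the largest change in each direction among genes past the threshold with a mean of at least 50 and no overlap between groups, leaving out predicted genes, clones, pseudogenes and receptor segments. Next are up to 3 members of each list with the lowest p and the 1 with the highest mean. Last are 13 genes of the sort and of oxidant metabolism. Some genes that the rule names are not reported here. A gene outside these kinds is marked as chosen after its values were seen.

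Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, equal library totals, quantile normalization, a robust prior, no trend, array weights, edgeR 4.0.16 on recovered reads (with the authors' size factors and with TMM), DESeq2 1.42.0 on recovered reads, and each library left out in turn. Ranges of adjusted p over the alternatives include those of edgeR and DESeq2. On the recovered reads edgeR called 7624 genes with the authors' size factors.

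The tests were tried on simulated data for HF against LF, with 14436 genes tested and known changes in a seeded set. limma recovered 8.33%, 32.7%, 61.2% and 77.6% of genes changed 1.5-, 2-, 4- and 8-fold, with 7 false calls among 14241 unchanged genes. edgeR recovered 8.33%, 32.7%, 57.1% and 75.5%, with 4 false calls. DESeq2 recovered 29.2%, 59.2%, 77.6% and 93.9%, with 97 false calls. A simulated list raised 2-fold was called by camera in 50 of 50 draws and an unchanged list in 0, without adjustment over lists. The simulated genes were drawn independently, so these draws cannot test the list calls for correlated genes. Among the real lists the estimated correlation was as high as 0.79 (mitochondrially encoded proteins). Both groups were simulated with the same spread, while the real HF libraries varied more than the libraries labelled LF.

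Pairs of libraries were compared over genes with at least 20 reads by the chi-square of their reads. The median per gene was 2.29 to 3 within the libraries labelled LF and 12.1 to 16.2 within HF, against 0.455 for sampling noise alone, so no 2 libraries agreed within sampling noise. Figures were drawn with matplotlib 3.10.9.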

Results

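RNA was sequenced from cells that the labels call neutrophils, sorted from the lungs of female C57BL6 mice in 2 groups named HF and LF. The labels do not spell these names out. Per the labels, the sort took CD45+ CD11b+ cells with low Ly6C and with Ly6G, a surface protein used to mark neutrophils. Libraries were made from 4 HF mice and 3 LF mice with a SMART-Seq kit, which amplifies complementary DNA from small amounts of RNA. The table held 35641 genes. Reads assigned to genes ranged from 13943173 to 16599658 in the HF libraries and from 16974428 to 18983351 in the libraries labelled LF. Genes with at least 1 read numbered 16743 to 26409 per HF library and 22362 to 24212 per library labelled LF. The design asks how lung neutrophils of HF mice differ from those of LF mice, and the study's title names oxidative stress in obesity.

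The sort markers were examined first. Ly6g (ENSMUSG00000022582), which encodes the Ly6G protein, averaged 3264 ± 1715 normalized counts (SD, n = 4) in HF and 2.99 ± 4.54 (SD, n = 3) in the libraries labelled LF, where the single values were 0.749, 0 and 8.22. S100a8 (ENSMUSG00000056054) and S100a9, which encode the calprotectin subunits that fill the neutrophil cytosol, stood at 41606 ± 5836 and 57401 ± 7262 in HF (SD, n = 4). They stood at 69.4 ± 4.29 and 56.2 ± 9.61 in the libraries labelled LF (SD, n = 3). The chemokine receptor Cxcr2 averaged 46723 in HF and 19.5 in the libraries labelled LF. Ly6c2, one of the genes of the Ly6C protein, went the other way, with 4193 ± 1589 in HF (SD, n = 4) and 13682 ± 1221 in the libraries labelled LF (SD, n = 3). Ptprc, which encodes CD45, and Itgam, which encodes CD11b, were present in all 7 libraries. Ptprc was higher in HF by 0.99 on the log2 scale, and this direction turned to -0.133 after quantile normalization. Itgam was higher by 1.16 (limma adjusted p = 3.5e-06). The other Ly6C gene, Ly6c1, averaged 78.0 and 28.6 and did not pass the test (limma adjusted p = 0.064). Without HF replicate 4 Ly6c1 did pass (limma adjusted p = 0.0061, with 0.0061 to 0.233 over the alternatives). Because the LF libraries went against the Ly6G+ Ly6Clo sort, they are called the libraries labelled LF throughout, and every direction given here is a difference between the HF libraries and those libraries.

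**Figure D1:**
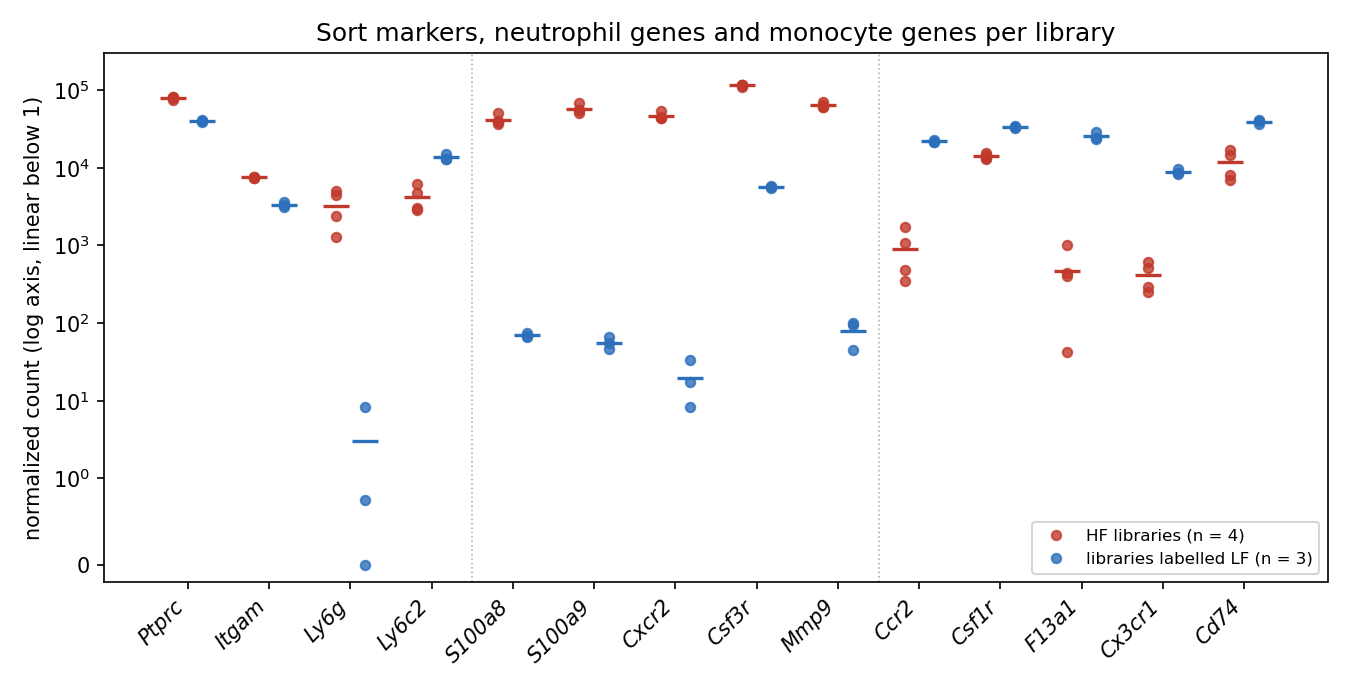
Normalized counts of sort markers, neutrophil genes and monocyte genes in each library (log axis, linear below 1; Ccr2 and F13a1 were chosen after their values were seen), with 1 point per library and a bar at the group mean (HF, n = 4, red; libraries labelled LF, n = 3, blue). S100a8 stood at 41606 in HF and at 69.4 in the libraries labelled LF, Ccr2 stood at 909 and 21847, and Ptprc was higher in HF except after quantile normalization (-0.133).

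Of 14 neutrophil markers tested, 13 were higher in HF and 0 were lower, with a median log2 difference of 7.64 (camera adjusted p = 1.7e-11, and adjusted p = 0.06 with an estimated correlation). Adjusted over the list alone, 14 were higher. In the libraries labelled LF, 7 of the 14 stood under 1% of their HF level. The highest, Cd177 (chosen after its values were seen), stood at 55.3% and was the 1 marker not past the threshold (limma adjusted p = 0.0642). Every other marker was higher in HF by at least 4.11 on the log2 scale. The receptor for granulocyte colony-stimulating factor, Csf3r, had the highest mean count of all genes in HF at 114715 ± 3601 (SD, n = 4), against 5670 ± 205 (SD, n = 3). Of 15 monocyte and interstitial macrophage markers, 12 were lower in HF and 0 were higher (12 and 0 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 8.2e-05, and adjusted p = 0.33 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, averaged 14073 in HF and 33667 in the libraries labelled LF, and the fractalkine receptor Cx3cr1 averaged 422 and 8875. The chemokine receptor Ccr2 and the coagulation factor gene F13a1, picked from this list after their values were seen, averaged 909 and 474 in HF and 21847 and 25478 in the libraries labelled LF. Of these 15 markers, 14 had a mean of at least 10 in HF as well. Of 13 dendritic cell and MHC class II genes, 10 were lower in HF and 1 was higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.34 with an estimated correlation). The invariant chain gene Cd74 averaged 11686 in HF and 38923 in the libraries labelled LF, and the class II transactivator Ciita averaged 114 and 1507. Of 11 platelet and megakaryocyte markers, 8 were higher in HF and 0 were lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.49 with an estimated correlation). The platelet integrin gene Itga2b averaged 277 ± 261 in HF (SD, n = 4), with 666 in HF replicate 3 and at most 184 in the other HF libraries. DESeq2 ended the call of the platelet list (adjusted p = 0.306, with 0.000225 to 0.306 over the alternatives).

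None of the other cell type lists passed the threshold. Adjusted over the list alone, their counts were those given here, except for the endothelial markers. Of 14 T cell markers and 10 NK cell markers, 0 passed the gene test (camera adjusted p = 0.94 and 0.17). The NK cell gene Nkg7 passed without HF replicate 1 (limma adjusted p = 0.0082, with 0.0082 to 0.185 over the alternatives), Klrd1 without HF replicate 4 (0.0194, with 0.0144 to 0.188) and Klra8 without HF replicate 3 (0.00175, with 0.00175 to 0.467). Of 11 B and plasma cell markers 4 were higher and 0 were lower (camera adjusted p = 0.17). The immunoglobulin gene Ighm did not pass, with 6346 in HF and 5938 in the libraries labelled LF, and its difference turned negative with equal library totals (-0.467) and after quantile normalization (-0.737). For eosinophil markers the counts were 3 higher and 0 lower of 5 (camera adjusted p = 0.069), for basophil and mast cell markers 1 and 0 of 8 (0.2), and for erythroid markers 3 and 0 of 6 (0.088). The NK cell list passed with no filter (camera adjusted p = 0.036, with 0.036 to 0.567 over the alternatives). The eosinophil list passed with no filter (0.00866), with equal library totals (0.0233) and without LF7 (0.0225, with 0.00866 to 0.273 over the alternatives). The erythroid list passed without HF replicate 3 (0.0382) and without LF8 (0.0475, with 0.0382 to 0.462 over the alternatives). The basophil and mast cell genes Cd200r3 and Ms4a2 passed without HF replicate 4 (limma adjusted p = 0.0116 and 0.0169, with 0.000327 to 0.189 and 0.0169 to 0.329 over the alternatives). Alveolar macrophage markers split, with 3 higher and 2 lower of 12 (camera adjusted p = 0.5). So did epithelial markers, with 4 higher and 3 lower of 14 (0.69). Endothelial markers had 0 higher and 2 lower of 10, and 0 of either adjusted over the list alone (0.94), with a median of 0.6, a mean of -0.07 and a test pointing up. Their calls, Kdr and Eng, were each lost without LF6, LF7 or LF8, among other alternatives (limma adjusted p = 0.123 and 0.0585 without LF7; over all alternatives, edgeR and DESeq2 included, 0.000988 to 0.199 and 0.00482 to 0.114). Fibroblast and smooth muscle markers had 1 higher and 2 lower of 8 (0.99), with a median of 0.35 that turned to -0.03 with equal library totals, a mean of -0.35 and a test pointing up. Among them the fibronectin gene Fn1, also made by monocytes, was lower in HF at 1098 against 34845. The smooth muscle actin gene Acta2 was higher at 1641 against 80.6. Precursor markers of immature neutrophils had 6 higher and 1 lower of 13 (camera adjusted p = 0.078), and passed with no filter (0.011), with a mean of at least 50 (0.0478) and with equal library totals (0.0163, with 0.011 to 0.123 over the alternatives). Of the adipocyte list only 2 members passed the filter on low values, too few for the list test, and 1 of them, the lipase gene Lipe, was higher in HF.

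Across all genes, 14936 had a mean of at least 10 normalized counts and were tested with limma. Of these, 8211 passed an adjusted p of 0.05, with 3917 higher and 4294 lower in HF than in the libraries labelled LF. With a log2 difference of at least 1 as well, the counts were 2818 and 3336. The 2 groups did not overlap in 9287 genes (62.2%), where chance gives 5.71%. The median log2 difference of all tested genes was -0.16. Setting all libraries to equal totals moved this median by -0.51 and gave 8988 calls, of which 30% were higher in HF, against 47.7% with the authors' scaling. Of these 8988, 7023 were among the 8211, and 32 of them had the opposite sign.

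Among genes with a mean of at least 50 that met the naming rule, the largest increase in HF on the log2 scale with a pseudocount of 1 was that of Ltf (lactoferrin). It averaged 28420 ± 24054 (SD, n = 4) in HF and 2.39 ± 0.971 (SD, n = 3) in the libraries labelled LF, a log2 difference of 12.76 ± 0.52 (SE). Ngp followed at 12.32, Il1f9 at 11.98, Asprv1 at 11.68, and Camp, the gene of the antimicrobial peptide cathelicidin, at 11.39. Cxcr2, Stfa2l1, Wfdc21, Dhrs9, Mrgpra2b and Steap4 lay between 11.35 and 10.86. Dhrs9 and Steap4 were uneven between the libraries labelled LF, highest in LF6 and lowest in LF8, with 48 and 18 reads in total. Their differences were 11.48 and 11.54 without LF6 and 10.05 and 10.21 without LF8. Ltf, Wfdc21, Camp, Asprv1, Stfa2l1 and Mrgpra2b had only 10, 10, 8, 6, 3 and 2 reads in these libraries. For Stfa2l1 and Mrgpra2b the ratio of means (HF over LF) had 95% intervals of 1660 to 23500 and 1620 to 48200 (counting error only). Amer2 averaged 1618 in HF and had 0 reads in the libraries labelled LF, which makes it at least 2230-fold higher (floor of 3 reads over the group, counting error only). On the log2 scale with a pseudocount of 1, the largest decreases under the same rule were of Tnfrsf11a, the receptor RANK, with a log2 difference of -7.86 ± 1.17 (SE), and of Endod1 at -7.85, Mx1 at -7.66, Stxbp6 at -7.62 and Arhgef37 at -7.58. Arsi, Clec10a (a macrophage lectin), Spic (a macrophage transcription factor), Galnt9, Ifi205 and Mfsd7a lay between -7.48 and -7.01. These genes were near 0 and uneven in HF, and single libraries moved their differences, which stayed past the threshold. Endod1, for example, stood at 0, 1.29, 0 and 25.7 and Mx1 at 0, 0, 115 and 83.4 in HF replicates 1 to 4. Without HF replicate 4 the differences of Tnfrsf11a, Endod1, Mx1, Stxbp6, Arhgef37, Arsi, Clec10a, Galnt9, Ifi205 and Mfsd7a lay between -9.005 and -8.055. Without HF replicate 3 those of Mx1 and Clec10a were -8.845 and -7.994, and those of Stxbp6, Arhgef37, Galnt9, Ifi205 and Mfsd7a lay between -6.626 and -6.217. Without HF replicate 2 those of Stxbp6 and Spic were -8.616 and -8.547, and those of Mx1 and Clec10a were -6.557 and -6.673. Without HF replicate 1 those of Mx1, Stxbp6, Clec10a, Galnt9 and Mfsd7a lay between -6.994 and -6.249. The order depends on the scale, and for these uneven genes the log2 difference exceeded that of the ratio of means, which was 86.4 for Tnfrsf11a, 96.6 for Endod1, 40.9 for Mx1, 68.7 for Stxbp6 and 64.5 for Arhgef37 and lay between 31.9 and 85 for the rest apart from Batf2 (LF over HF). Single HF libraries set these ratios too: in HF replicates 1 to 4 Tnfrsf11a stood at 0, 0, 1.12 and 29.5, and Arsi at 0, 0, 0 and 24.4. Batf2 had 0 reads in HF and 130 normalized counts in the libraries labelled LF, which makes it at least 144-fold lower. Ltf, Ngp, Camp, Stfa2l1, Wfdc21, Mrgpra2b and Cxcr2 belong to the lists of neutrophil genes, while Il1f9, Asprv1, Dhrs9, Steap4 and Amer2 are in none of the lists. The median neutrophil marker in the libraries labelled LF stood at 0.86% of its HF level.

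Genes of oxidant production were mostly higher in HF. Of 15 genes of the NADPH oxidase list, 10 were higher, 2 were lower and 3 did not pass, with the same 10 and 2 counts adjusted over the list alone (camera adjusted p = 8e-04, and adjusted p = 0.34 with an estimated correlation). The list includes S100a8 and S100a9, which are also among the neutrophil markers. The cytosolic subunits Ncf1 and Ncf4 were higher by 1.58 ± 0.14 and 1.03 ± 0.1 (SE), and the GTPase gene Rac2 by 2.31 ± 0.07 (SE). Cybb (ENSMUSG00000015340), the catalytic subunit of the oxidase, was lower, at 8236 ± 3263 in HF (SD, n = 4) and 37027 ± 718 in the libraries labelled LF (SD, n = 3). Its partner Cyba was higher by 0.57 ± 0.06 (SE), but by 0.052 with equal library totals (limma adjusted p = 0.441), and it was lower by quantile normalization at -0.24. Quantile normalization also ended the call of the list (adjusted p = 0.346, with 4.66e-11 to 0.346 over the alternatives). Neutrophil and monocyte markers differed between the same libraries by medians of 7.64 and -2.66.

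Of 29 antioxidant genes, 14 were higher and 12 were lower in HF (14 and 13 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.64). Its median was -0.16 and its mean -0.03, while the test pointed up, and its test turned to down after quantile normalization. Thioredoxin (Txn1) was higher by 2.51 ± 0.08 (SE), and glutathione reductase (Gsr) by 1.88 ± 0.08 (SE). Peroxiredoxin 1 (Prdx1) was lower by 2.78 on the log2 scale, from 8014 ± 70.6 in the libraries labelled LF (SD, n = 3) to 1171 ± 115 in HF (SD, n = 4), catalase (Cat) had a difference of -2.19 ± 0.26 (SE), and mitochondrial superoxide dismutase (Sod2) one of -0.87 ± 0.18 (SE). Cytosolic superoxide dismutase (Sod1) averaged 516 and 684 and did not pass (limma adjusted p = 0.067), but it was lower without HF replicate 1 (0.0128, with 0.00245 to 0.348 over the alternatives). The 7.64 of the neutrophil markers and the -2.66 of the monocyte markers apply here too.

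**Figure D2:**
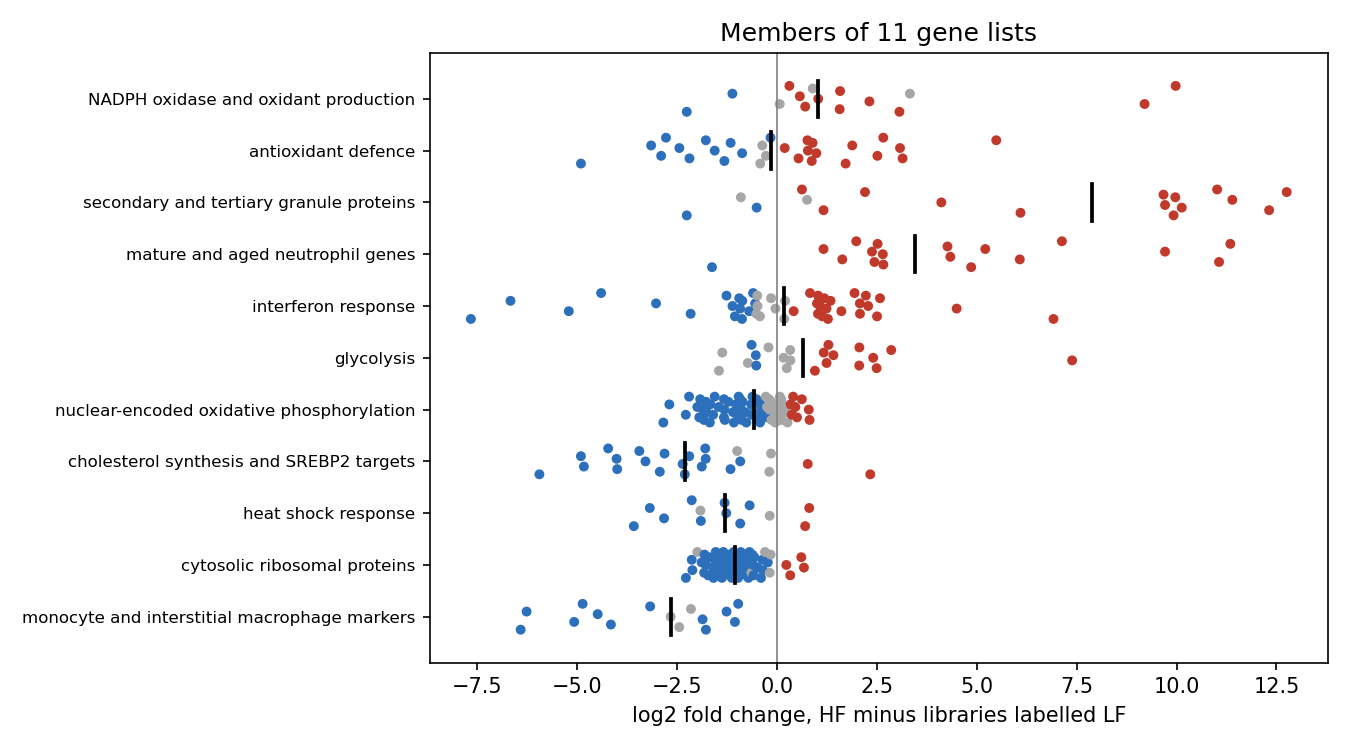
Log2 differences between HF (n = 4) and the libraries labelled LF (n = 3) for the tested members of 11 gene lists, 1 point per gene (red higher and blue lower in HF past an adjusted p of 0.05 by limma, grey not past), with a black bar at the list median. The median was 1.03 for the NADPH oxidase list and -1.06 for the ribosomal proteins, and it kept its sign under each scaling tried for every list drawn except the interferon response, whose median of 0.18 turned to -0.34 with equal library totals and to -0.15 after quantile normalization.

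Secondary and tertiary granule genes and genes of mature neutrophils were higher in HF as groups, and primary granule genes did not pass as a group. Of 18 secondary and tertiary granule genes, 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with a median of 7.88 (camera adjusted p = 2.2e-06, and adjusted p = 0.34 with an estimated correlation). Mmp9 (gelatinase) averaged 64131 ± 3885 in HF (SD, n = 4) and 80.1 ± 30.6 in the libraries labelled LF (SD, n = 3), and Lcn2 (lipocalin) averaged 21834 and 20.3. The lysozyme gene Lyz2, shared with macrophages, was lower in HF by 0.51 on the log2 scale, a difference of -0.51 ± 0.12 (SE). Of 18 genes of mature and aged neutrophils, 17 were higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 1.1e-10, and adjusted p = 0.06 with an estimated correlation). The cytokine gene Il1b averaged 92246 and 2501. Of 10 primary granule and NET genes, 6 were higher and 2 lower (camera adjusted p = 0.23), with Padi4, the enzyme that citrullinates histones, higher by 3.6 and Ctsc, which activates granule proteases, lower at -3.49. Adjusted over the list alone, 6 were higher and 3 lower. In the libraries labelled LF the median neutrophil marker stood at 0.86% of its HF level. Within HF, replicate 1 stood above the other libraries in Ltf, at 64160 against 12470 to 20500, and in Camp, at 17780 against 5131 to 6465. Alveolar macrophage markers were also higher there, in 7 of 10 genes above every other HF library, with a median log2 difference of 2.

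**Figure D3:**
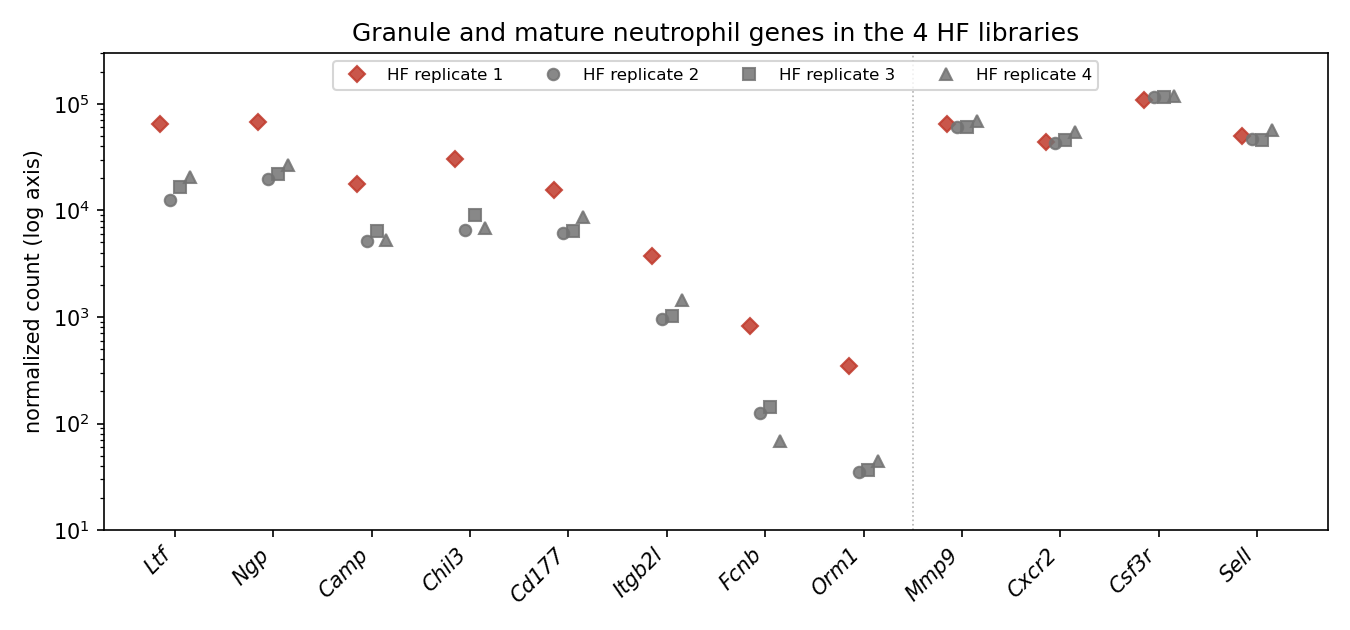
Normalized counts (log axis) of 8 genes, chosen after their values were seen, and of 4 genes of mature neutrophils in the 4 HF libraries, 1 point per library (red diamonds, HF replicate 1; grey circles, squares and triangles, replicates 2, 3 and 4). The 8 are granule genes and the precursor marker Fcnb, and all 8 were highest in HF replicate 1. Of the 18 members of the granule list, only 9 were. Mmp9, drawn with the mature genes, is also in the granule list. Ltf stood at 64160 in HF replicate 1 and at 12470 to 20500 in the others, while Mmp9 lay between 61061 and 69301 in all 4.

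Signalling genes followed. Of 26 chemokine and cytokine genes, 16 were higher and 7 lower in HF (17 and 8 adjusted over the list alone; camera adjusted p = 0.0044, and adjusted p = 0.2 with an estimated correlation), with Il1b at 92246 against 2501 and Tnfsf14 at 4427 against 140. Of 19 chemoattractant receptors, 15 were higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 1e-05, and adjusted p = 0.19 with an estimated correlation), among them the complement receptor C5ar1 at 25062 against 699 and Ccr1 at 31915 against 375. Of 20 immediate early genes, 14 were higher and 4 lower (14 and 4 adjusted over the list alone; camera adjusted p = 0.00018, and adjusted p = 0.35 with an estimated correlation), with the phosphatase gene Dusp1 at 86561 against 22734. Of 17 immune suppression genes, 13 were higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 7.5e-06, and adjusted p = 0.2 with an estimated correlation), with Trem1 higher by 5.48 and Ptgs2 by 6.78. Of 18 hypoxia and angiogenic genes, 11 were higher and 3 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.0044, and adjusted p = 0.19 with an estimated correlation). The TNF and NF-kB list had 15 higher and 11 lower of 29 (17 and 11 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.64 with an estimated correlation). Its call ended with no mean-variance trend (adjusted p = 0.0613), by edgeR with the authors' size factors (0.0657) and with TMM (0.0652), without HF replicate 2 (adjusted p = 0.064) and without HF replicate 3 (adjusted p = 0.0514, with 6.6e-05 to 0.118 over the alternatives). The Toll-like receptor and inflammasome list had 16 higher and 8 lower of 29 (16 and 8 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.34 with an estimated correlation), with Nlrp12 at 12327 against 10.7. Quantile normalization ended both calls, with adjusted p of 0.118 and 0.0898 (the latter list ranged from 1.32e-05 to 0.0898 over the alternatives). The libraries labelled LF, whose median neutrophil marker stood at 0.86% of its HF level, are the lower side of these lists.

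Other immune lists moved both ways. Of 25 adhesion and transmigration genes, 11 were higher and 11 lower (12 and 11 adjusted over the list alone; camera adjusted p = 0.15), and the median of 0.69 turned to -0.13 after quantile normalization, with Jaml higher by 5.31 and Cd44 by 1.96. The list passed by DESeq2 (adjusted p = 3.08e-06) and with no filter (0.0314, with 3.08e-06 to 0.853 over the alternatives). Of 45 interferon response genes, 21 were higher and 16 lower (21 and 19 adjusted over the list alone; camera adjusted p = 0.24), with Ifitm1 higher by 6.92 and Mx1 lower at -7.66. Of 24 apoptosis regulators, 10 were higher and 5 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.17), and the median of 0.26 turned to -0.26 with equal library totals, with the survival gene Mcl1 at 61373 against 21157. That list passed with no filter (adjusted p = 0.0489, with 0.0489 to 0.432 over the alternatives). Of 30 cell cycle genes, 3 were higher and 5 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.69), and the median of -0.33 turned to 0.41 by edgeR with TMM, with the replication factor Pcna at 471 against 1120. None of these 4 lists passed. The median neutrophil marker in the libraries labelled LF stood at 0.86% of its HF level.

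Lists of oxidative phosphorylation genes and of ribosomal proteins were lower in HF, though not in all members. Of 75 nuclear-encoded oxidative phosphorylation genes, 47 were lower and 8 higher (47 and 8 adjusted over the list alone; camera adjusted p = 6.2e-05, and adjusted p = 0.56 with an estimated correlation), with Ndufa11 at 191 against 933 and cytochrome c1 (Cyc1) at 481 against 1535. Of 12 mitochondrially encoded genes, 7 were lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.65 with an estimated correlation), with mt-Co1 at 14201 against 22069. This call ended without HF replicate 4 (adjusted p = 0.0671) and without the LF-labelled library LF7 (adjusted p = 0.0586), and with DESeq2 (adjusted p = 0.183, with 0.00149 to 0.183 over the alternatives). Of 77 cytosolic ribosomal protein genes, 69 were lower and 4 higher (69 and 4 adjusted over the list alone; camera adjusted p = 4.8e-14, and adjusted p = 0.26 with an estimated correlation), with Rpl4 at 1506 against 5159. Rps9 was among the 4, higher by 0.67, and turned to -0.135 after quantile normalization. Of 13 heat shock genes, 9 were lower and 2 higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.0051, and adjusted p = 0.23 with an estimated correlation), with the inducible chaperone Hspa1a at 778 against 9183. Hspa1a is uncertain, since it and Hspa1b are near-identical copies that can share reads. Monocyte markers were also lower in HF, with a median of -2.66.

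In the sugar and lipid lists, 11 of 22 glycolysis genes were higher and 3 lower in HF (11 and 4 adjusted over the list alone; camera adjusted p = 0.004, and adjusted p = 0.4 with an estimated correlation), led by the glucose transporter Slc2a3 at 22230 against 134. Quantile normalization ended the glycolysis call (adjusted p = 0.0687, with 5.13e-06 to 0.0687 over the alternatives). Of 23 genes of cholesterol synthesis, 18 were lower and 2 higher (18 and 2 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation). Srebf2, a transcription factor of cholesterol synthesis, had a difference of -1.8, while Sc5d was higher by 2.33. Fatty acid uptake and oxidation genes went both ways, with 8 higher and 13 lower of 33 (8 and 13 adjusted over the list alone; camera adjusted p = 0.98), a median of -0.19, a mean of 0.25 and a test pointing up. The lipolysis regulators G0s2 and Pnpla2 were higher by 4.53 and 2.86. Fatty acid synthesis genes had 2 higher and 7 lower of 13 (2 and 8 adjusted over the list alone; camera adjusted p = 0.13), and passed with no filter (adjusted p = 0.0135, with 0.0135 to 0.288 over the alternatives). Cholesterol efflux genes had 3 higher and 5 lower of 10 (3 and 5 adjusted over the list alone; camera adjusted p = 0.3), with the efflux apolipoprotein gene Apoe at 3694 against 13345. The pentose phosphate list had 4 higher and 5 lower of 14 (4 and 5 adjusted over the list alone; camera adjusted p = 0.94), a mean of -0.25, a test pointing up and a median of 0.12 that turned to -0.4 with equal library totals and to -0.31 after quantile normalization, with Taldo1 higher by 2.16 and Idh1 lower at -2.57. The unfolded protein list had 8 higher and 13 lower of 24 (10 and 13 adjusted over the list alone; camera adjusted p = 0.51), a median of -0.56, a mean of 0.2 and a test pointing down, with Ddit3 higher by 3.11. The chaperone Hspa5 did not pass, at 10723 against 10641, and was lower with equal library totals (-0.516) and after quantile normalization (-0.889). The median neutrophil marker in the libraries labelled LF stood at 0.86% of its HF level.

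In total, 20 of 42 lists passed the threshold, 13 toward higher and 7 toward lower values in HF, with a preset correlation of 0.01 between genes. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.06. The rotation test fry, which asks only whether the genes of a list move one way on balance, gave 30 lists.

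In the authors' deposited table, 8806 genes had an adjusted p under 0.05, of which 4550 were higher and 4256 lower in HF. Of these genes, 7935 also passed limma here, and all 7935 had the same sign. All 3 libraries labelled LF had a median neutrophil marker of at most 138, against at least 19500 in HF, so no comparison remains when the libraries in doubt are left out.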

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

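The tests of explanations for the 3 patterns were chosen only after the results were seen, while the comparison with other splits of the libraries was planned. Among 163 sets of 4 HF values, 23 had 1 library far from the other 3. The rule flags about 5% of sets of normally distributed values. That share does not apply to these untransformed counts, some of genes named for being low in HF, so the 23 is not a test against chance. The libraries labelled LF are too few for this rule.

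In HF replicate 1, Ltf (64160, others 12470 to 20500), Ngp (67280, others 19660 to 26680), Camp (17780, others 5131 to 6465), Idh1 (1742) and G0s2 (5057) stood above the other HF libraries. In HF replicate 2, Asprv1 (9109), Spic (28.29), Kdr (20.57) and Pdgfrb (12.86) did, the last 3 with 0 in the others. HF replicate 3 was high in Calcrl (1060), Itga2b (666) and Klra8 (34.76), and low in Sesn2 (2594) and Hbb-bs (2767). HF replicate 4 was high in Tnfrsf11a (29.5), Endod1 (25.66), Arhgef37 (132.1), Arsi (24.37), Ifi205 (89.8), Mfsd7a (71.84), Hk3 (11610), Tk1 (32.07) and Rpl4 (1781).

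The count of 8211 genes exceeded that of every other split of the 7 libraries into 4 and 3. In 1 of 35 splits, the real one, as many genes passed, and the highest other count was 53. This argues against a random grouping of these libraries, but 1 of 35 is the lowest share that the comparison can give, so chance is not excluded. Every other split mixes HF libraries with libraries labelled LF, and the comparison does not tell what sets the 2 groups apart. For gene lists, 10 of 35 splits gave at least the 20 of the real split, and the highest other split gave 23. The other splits that gave at least 20 kept most or all libraries labelled LF on 1 side, so they carry part of the same difference. The comparison therefore cannot decide on chance for the number of lists called with the preset correlation, and chance is not excluded.

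The first pattern is that the libraries labelled LF held few neutrophil transcripts and many monocyte transcripts. A swap between an HF library and one labelled LF is argued against, since 0 HF libraries had a median neutrophil marker at or below the highest labelled LF (138 against at least 19500). A candidate explanation is that the libraries labelled LF came mostly from another cell type, such as monocytes. The median neutrophil marker stood at 0.86% of its HF level, and Ccr2, Csf1r and F13a1 reached 21847, 33667 and 25478. A gate on Ly6G+ and low Ly6C should remove monocytes, however. Of the 15 monocyte markers, 14 had a mean of at least 10 in HF too, but 12 were lower there and 0 were higher. Of the 14 neutrophil markers, 7 stood under 1% of their HF level. Only Cd177 (chosen after its values were seen), at 55.3%, stayed near its HF level, and every other marker was higher in HF by at least 4.11 on the log2 scale. A whole set of libraries from outside the sort, or wrong labels for all 3, stays open, and the column numbers 6 to 8 do not match those of the labels. The markers as a set argue against a difference between HF and LF neutrophils as the whole pattern. The median neutrophil marker stood at 0.86% and Ly6g at 0.092% of the HF level. Finer differences between HF and LF neutrophils cannot be told apart from the rest of the pattern, since 0 libraries labelled LF carried Ly6g at 50% of the HF mean.

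The second pattern is that genes varied more between HF libraries than between the libraries labelled LF. Among tested genes, 56 to 153 per HF pair had 0 in 1 library and at least 100 in the other, against 0 to 3 per pair labelled LF. Depth is argued against as the whole cause, because with every library thinned to the 13943173 reads of HF replicate 2 the highest chi-square per degree of freedom of a pair labelled LF was 8.1 and the lowest of an HF pair was 31.9. Whether fewer RNA molecules were amplified per HF library is not settled. Below a mean of 1000 the excess variance over the mean in HF rose with a log-log slope of only 0.11, from 16.1 to 24.4. In the libraries labelled LF it rose from 0.973 to 2.65 between mean levels of 16.74 and 556.8. That is a larger relative rise than in HF, but still small beside the rise of the mean level. No slope was fitted for the libraries labelled LF, so whether the slope sets HF apart was not tested. The higher HF value in every bin restates the pattern. HF replicate 2 goes the other way, with the most genes detected (26409) and 479 tested genes at 0, against 340 to 513 in the libraries labelled LF. Differences between the HF mice stay open and were not tested.

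The third pattern is that secondary granule genes stood higher in HF replicate 1, with a median log2 difference of 0.49 over 18 genes, 9 of which were above every other HF library while Hp (like Chil3, Ccr2 and F13a1 here, chosen after its values were seen), Itgam and Mmp9 had -0.1, -0.01 and 0.03. The size factor of this library is argued against, since the median over 10094 genes was 0.01, and alveolar macrophage RNA is argued against as the whole cause: although 7 of 10 macrophage markers were above every other HF library, with a median log2 difference of 2, they rose by only 3.43% of the median rise of the granule genes (133 against 3890 normalized counts), and a part of the rise of Chil3, which these macrophages also make, stays open. A larger share of immature neutrophils is a candidate, with mixed markers: precursor markers outside the granule list had a median of 0.72, with 4 of 10 above every other HF library, at percentile 97.4 of random lists, while mature neutrophil genes had 0. Mpo (6.92), Elane (10.4), Ctsg (8.07), Prtn3 (23.1), Mki67 (560) and Tuba1b (420), chosen after their values were seen, were each higher in another HF library. Of these, Mpo, Elane, Ctsg and Prtn3 had few reads, at 42.3 or less in every HF library. No biological explanation is given by the design, since all 4 libraries are HF.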

How the results depend on the processing

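All settings were planned. No paired analysis was possible because the LF columns carry no replicate number of the labels, and the planned fit with such a block was not run. Total calls stayed within 1.5 times of 8211, from 7263 to 9024 with all libraries (with a log2 difference of at least 1 as well, 2818 higher and 3336 lower remained) and from 6450 to 8464 with 1 left out. Without 1 library labelled LF they were 6450 to 6489, and without 1 HF library 8210 to 8464. The total number of libraries was the same in both cases but the number per group was not, so these fits cannot tell whether group size set the lower counts. Their cause was not tested. Of 144 named genes past the threshold, 137 kept direction and side in every setting, and of 20 lists 14 did. Of 795 values of the 42 lists, 738 kept both, 13 lost the call, 13 gained it and 31 changed direction. Over 42 lists, 20 passed, and 0 did with an estimated correlation in camera, and the cause was not tested.

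With equal library totals these directions turned (log2 values; the cause was not tested beyond the shift of -0.51 in the median gene): Hspa5 -0.516, Ighm -0.467, and the pentose phosphate list, median -0.396. After quantile normalization, Ptprc was -0.133, Cyba -0.24, Hspa5 -0.889, Rps9 -0.135 and Ighm -0.737. List tests turned there too, at medians of -0.152 (antioxidant), -0.126 (adhesion), -0.149 (interferon), -0.31 (pentose phosphate) and 0.443 (T cell), and the cause was not tested. Hspa5 was -0.017 with array weights and -0.012 by edgeR with TMM.

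The tests of the following lists, none past the threshold, turned with no cause tested, at these medians. Fatty acid uptake had -0.298 with a mean of at least 50, -0.172 with array weights, -0.101 by edgeR with the authors' size factors and -0.128 with TMM. Cell cycle had 0.435 and 0.414 by edgeR with these factors and TMM. The pentose phosphate list had 0.118 with no trend. Epithelial markers had 0.65 with a mean of at least 50 and 1.617 by DESeq2. Endothelial markers had 0.476 with no filter and 0.959 by DESeq2. Fibroblast markers had 0.076 with a pseudocount of 0.5 and 0.478 with no filter. Leaving out 1 library, values ranged from -0.088 to 0.07 for Hspa5, from -0.089 to 0.242 for Ighm, and for lists from -0.067 to 0.167 (pentose phosphate), -0.291 to -0.071 (fatty acid uptake), -0.732 to 0.382 (cell cycle), 0.177 to 0.83 (endothelial), -0.756 to 1.572 (fibroblast) and -0.318 to 0.322 (T cell). Depth limits genes near 1 read, which is worth 0.685 to 1.29 normalized counts.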

Other observations

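Genes outside the fixed lists also separated the HF libraries from the libraries labelled LF, and they were picked here after their values were seen, from the 25 most abundant genes of each group, and each passed the limma test. Mxd1, a MAX-binding repressor of MYC target genes, averaged 90717 ± 8055 in HF (SD, n = 4) and 880 in the libraries labelled LF. Lilr4b, an inhibitory receptor gene, averaged 68704 and 3353, Fgl2 55199 and 4846, and Cd33 44078 and 801. Psap, a lysosomal protein gene, averaged 62520 in the libraries labelled LF and 28216 in HF. Ahnak averaged 24775 in the libraries labelled LF and 1720 in HF, and the lysosomal proteases Ctss and Ctsb averaged 24600 and 30858 against 4764 and 10626.

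By a rule set after values were seen, of 3227 genes with an HF mean of at least 1000, 2 had a highest HF library at least 32-fold above the lowest. Retnla, a resistin-like gene of macrophages and eosinophils, stood at 1.15, 23.1, 13669 and 3615 in HF replicates 1 to 4 and at 1105, 782 and 6.85 in LF6, LF7 and LF8. Lyz1, a lysozyme gene close in sequence to Lyz2, stood at 159, 39.9, 6675 and 227 in the HF replicates and at 1401, 1170 and 695 in LF6, LF7 and LF8. Among list members chosen after their values were seen, HF replicate 3 was also highest in the platelet genes Ppbp (1612, others at most 354) and Pf4 (673, others at most 308) and in the complement gene C1qb (2028, others at most 553). HF replicate 1 was highest in the alveolar macrophage markers Atp6v0d2 (703), Plet1 (435) and Krt79 (193), chosen in the same way.

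The authors' deposited table holds 17 genes with a log2 fold change beyond 20. All 17 had reads in a single library, and 0 of them had an adjusted p.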
